A study of Mus musculus with 7 samples.

How the data were processed

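The series holds 7 CEL-seq libraries of single cells from mammary tumours of mice that carry the polyoma middle T transgene (PyMT), a mouse model of breast cancer. CEL-seq tags each cell's RNA with a cell barcode and each molecule with a molecular barcode, and reads the 3' end of transcripts. Per the labels' protocols, cells were sorted into Trizol, RNA was precipitated with GlycoBlue and libraries were read paired-end on an Illumina NextSeq 500. In experiment (i), 3 libraries of 96 wells each held tumour cells sorted as positive for E-cadherin (Ecad), the adhesion protein encoded by Cdh1. In experiment (ii), 4 libraries held cells of up to 4 sorted populations. They are called TEpos and TEneg here (labelled solid tumour, Ecad-positive and Ecad-negative) and BEneg and BEpos (labelled circulating tumour cells, Ecad-negative and Ecad-positive). Each of the 4 libraries held 24 wells of TEpos, TEneg and BEneg, and library 1 also held 24 wells of BEpos, which gave 312 wells. The deposited barcode table ties every well to its library and population, and each well was meant to receive 1 sorted cell, so no doublet caller was run. One TEneg well of library 2 with over 20000 transcripts was left out in an alternative chosen after the data were examined.

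The deposited values are estimated counts of transcripts per gene and well, not normalized between wells. Per the submitters' processing notes, reads were mapped with BWA 0.6.2-r126 and the genome build was mm10. The counting step is not given in the sources used here. Every deposited value equals 256 times the natural logarithm of 256/(256 − k) for a whole number k, with a largest distance from a whole number of 3.1e-13. That is the estimate of molecules sampled from the 256 molecular barcodes that 4 bases allow. Genes captured more often than the barcodes can resolve are therefore compressed before and stretched after this estimate, which adds noise to the most abundant genes of large cells. Spike-in transcripts were left out of all totals. The table of experiment (ii) held 11753 genes and 73 spike-ins. Reads shared by near-identical copies, such as ribosomal protein genes and their pseudogenes or Lyz1 and Lyz2, may have been split between genes, since no rule for shared reads is given in the sources used here, and values of these genes are uncertain to that extent.

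Wells with at least 500 transcripts of named mouse genes were used. This left 220 of the 312 wells of experiment (ii), namely 71 TEpos, 69 TEneg, 60 BEneg and 20 BEpos cells. Cells are not replicates, so transcripts were summed per library and population wherever at least 3 cells were left, and the estimated counts were rounded to whole numbers. The library is the replicate (n = 4). Nothing in the labels says that libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Sums of the same population differed by more than sampling noise in every pair of libraries (chi-square per degree of freedom from 1.87 to 4.35), so no sum was a copy of another, which says nothing on whether the libraries are independent samples.

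TEpos, TEneg and BEneg sums were fitted together with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, which left 490 genes) with library as a block, under R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The pairing comes from the design, since the barcode table places the populations in the same libraries. Residuals of the same library correlated at 0.0608 to 0.351 between populations, with means of 0.188 for TEneg with TEpos, 0.167 for BEneg with TEneg and 0.205 for BEneg with TEpos. BEpos was in 1 library and was not tested, and its values carry exact Poisson intervals. The 95% intervals, binomial ones being exact Clopper-Pearson intervals, cover counting error only, except those of the ratios of 6 luminal and epithelial genes between wells sorted from blood, which come from resampling wells within libraries and cover the spread between wells.

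Before the data were examined, 24 gene lists were fixed: epithelial, mesenchymal, transcription factors of epithelial-to-mesenchymal transition (EMT), luminal mammary, basal and myoepithelial, stem cell associated, proliferation, leukocyte, T and NK cell, B cell, monocyte and macrophage, neutrophil, MHC class II, platelet, erythroid, endothelial, fibroblast, interferon response, immediate early and stress, glycolysis and hypoxia, oxidative phosphorylation, TGF-beta response, mitochondrially encoded and cytosolic ribosomal protein genes. Of the mitochondrially encoded list, 0 genes were measured here, so it has no result. Lists with at least 3 tested genes were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, and also with an estimated correlation, and p-values were adjusted over the lists of a comparison. No list call was kept with the estimated correlation. The fry test of limma, which asks whether a list's genes move one way on balance without comparing them with other genes, was run beside it. For each list the share of transcripts per library and population was also computed, with an exact two-sided sign-flip permutation test of the within-library differences. With 4 libraries this test cannot reach 0.05, and its smallest p is 0.13, so list shares are given as levels with the number of libraries in each direction.

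Named genes followed a rule fixed before the data were examined: the 10 called genes with the largest fold in each direction that moved the same way in all 4 libraries, 12 fixed genes and Ptprc where measured, and up to 4 highest expressed members of each list. Predicted genes, Rik genes and pseudogenes were left out. Of 76 named genes, 72 were found in GENCODE M21 on GRCm38, the assembly that mm10 denotes, and all 72 lay on the chromosome given in the deposited table. A fold against a population with 0 transcripts is a lower bound computed with 3 transcripts over the whole population. It leaves out the counting error of the other population and the spread between libraries, so it is not a confidence bound. A fold against 1 to 3 transcripts is a ratio of transcripts per total with its exact interval.

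Simulated sums drawn from the real means and totals of the 490 genes, with 200 genes changed, were used to test the scripts. Percentages are of the genes that passed the filter in the simulated sums, so changed genes that failed it are not counted as missed. For TEneg versus TEpos 427 of 490 genes passed, with 58, 59 and 55 of the genes changed 2-fold, 4-fold and 8-fold among them. Of these, 77.6%, 100% and 100% were called, and 2.75% of unchanged genes that passed. For BEneg versus TEneg the values were 70.8%, 98.4%, 100% and 3.05%, and for BEneg versus TEpos 76.2%, 96.8%, 100% and 4.03%. In each comparison a list of 10 raised genes was called and 0 of 20 lists of unchanged genes. Simulated genes were drawn independently of each other, and the raised genes were raised at least 2-fold. These list results therefore check that the scripts run as meant, and cannot show how camera with the preset correlation behaves on correlated genes.

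Alternatives fixed beforehand were no library block, DESeq2 size factors, scaling by total transcripts alone, the DESeq2 1.42.0 Wald test and no filter on low counts. Also fixed were a filter of at least 10 transcripts in 4 sums, no minimum per cell, and a minimum of 1500 transcripts per cell. The last left BEneg sums in libraries 1 and 2 only. Others fixed beforehand were cells thinned to 500 transcripts, only the 2 populations compared, cells with 2 or more leukocyte transcripts left out, and each library left out in turn. A further one, called means of cells, averaged the CPM of cells in each sum and tested log2(mean CPM + 10) with limma. Alternatives added after the data were examined left out the largest TEneg cell, or TEneg cells above every TEpos cell in endothelial, basal or immune lists. Shares of cells with a transcript were also computed with every cell thinned to 500 transcripts. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Library 3 of experiment (i) gave 1 cell of at least 500 transcripts and is left out of means over libraries.

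Some rules of the closing tests were changed after results had been seen. Medians of mesenchymal genes were moved to a fixed gene set with Tgfbi, which had 0 transcripts in TEpos, at its lower bound. An explanation was taken as excluded only where its bound was passed by more than the spread. TEneg was added to TEpos as a possible source of Cdh1 transcripts in BEneg, low-yield wells were weighed in the test of an equal background, and the test of these wells was corrected to include BEpos wells. The share of other splits of the sums was judged on the splits within libraries alone, since the populations share libraries.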

Results

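Single cells of PyMT mouse mammary tumours were profiled by CEL-seq to compare epithelial and mesenchymal states of tumour cells and of cells sorted from blood as circulating tumour cells. Experiment (ii) gave 71 TEpos, 69 TEneg, 60 BEneg and 20 BEpos cells of at least 500 transcripts. Transcripts of all sorted wells came to 201007, 210520, 68589 and 63117 in libraries 1 to 4. The sums per library and population ran from 27416 to 71894 in TEpos, from 17189 to 109892 in TEneg and from 11172 to 25379 in BEneg, and the BEpos sum was 75125. Used cells had a median of 2064 transcripts in TEpos, 1603 in TEneg, 819 in BEneg and 3803 in BEpos. A single TEneg cell of library 2 held 61227 transcripts, 55.7% of its sum. In experiment (i), 95, 65 and 1 of 96 wells in libraries 1 to 3 reached 500 transcripts, and all wells together held 438171, 76783 and 14046 transcripts.

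The first comparison asked how Ecad-negative tumour cells differed from Ecad-positive ones. Sparc, Col4a1, Col4a2, Igfbp3, Acta2 and Vim transcripts were higher in TEneg, and Wfdc18, Csn3, Fos and Zfp36 transcripts were lower. Sparc, a secreted collagen-binding protein, averaged 37.9 ± 11.4 transcripts per 10000 in TEneg against 3.49 ± 1.54 in TEpos (SD, n = 4 libraries), a log2 fold change of 3.45 (SE 0.25, edgeR adjusted p = 9.36e-11). The type IV collagen genes Col4a1 and Col4a2 rose by 4.44 (SE 0.38) and 3.98 (SE 0.44) on the log2 scale, and Col4a1 went from 1.203 ± 1.10 to 25.1 ± 5.92 per 10000. Igfbp3, an insulin-like growth factor binding protein, rose by 3.89 (SE 0.46). Cdh1 itself, whose protein defined the sort, did not pass the test, at 4.16 ± 1.94 per 10000 in TEneg and 5.87 ± 3.37 in TEpos (log2 fold change 0.01, SE 0.32, edgeR adjusted p = 0.995, higher in TEneg in 2 of 4 libraries). Of 490 genes tested with edgeR, 31 were called, 23 higher and 8 lower in TEneg, and all named here as called moved the same way in 4 of 4 libraries unless stated.

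Among the mesenchymal genes, 4 of 7 tested members rose and none fell, and 6 rose adjusted over the list alone. The intermediate filament gene Vim rose by 2.48 (SE 0.32, adjusted p = 1.81e-06), from 2.15 ± 0.587 to 12.5 ± 7.17 per 10000. Smooth muscle actin (Acta2) rose by 3.78 (SE 0.43, adjusted p = 2.46e-07), from 1.42 ± 0.705 to 24.7 ± 20.8 per 10000, and the proteoglycan gene Bgn by 2.35 (SE 0.52, adjusted p = 0.0039). The list was called by camera (adjusted p = 4.97e-07, median log2 fold change 2.48, and adjusted p = 0.0782 with an estimated correlation). Tgfbi had 10 transcripts in TEneg and 0 in TEpos, at least 3.45-fold higher, and did not pass (adjusted p = 0.0596). Mesenchymal genes took 1.204 ± 0.625% of TEneg and 0.188 ± 0.0267% of TEpos transcripts, higher in 4 of 4 libraries. Markers of other cell types moved with them: endothelial genes took 0.140 ± 0.0604% of TEneg against 0.0210 ± 0.0238% of TEpos, basal and myoepithelial genes, which include Acta2, 0.477 ± 0.371% against 0.0317 ± 0.00709%, and fibroblast genes 0.175 ± 0.102% against 0.0559 ± 0.0139%, each higher in 4 of 4 libraries. Of 69 TEneg cells, 16 lay above every TEpos cell in the endothelial share and 15 in the basal share, with 0 in both. Of the 10 TEneg cells above every TEpos cell in the mesenchymal share, 9 were among these. In all, 36 of the 69 TEneg cells lay above every TEpos cell in endothelial, basal or immune genes. With these left out, Sparc stayed called at 2.61 and Vim, at 1.42, did not (adjusted p = 0.231).

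Transcription factors of EMT were too low to test. Their share was 0.0399 ± 0.0163% in TEneg and 0.0133 ± 0.00253% in TEpos, higher in 4 of 4 libraries. Snai2 had 4, 6, 0 and 2 transcripts in TEneg libraries 1 to 4 and 0 in TEpos. Zeb1 had 2, 6, 1 and 2 in TEneg and 0 in TEpos. Cdh2, encoding N-cadherin, had 1, 3, 1 and 2 in TEneg and 0 in TEpos. Snai1, Twist1 and Zeb2 had at most 3 transcripts in any TEpos or TEneg sum. Of the TGF-beta response list 1 of 3 tested genes rose, and 2 adjusted over the list alone. That gene was Pmepa1, a TGF-beta target (log2 fold change 1.21, SE 0.27, adjusted p = 0.0039), and the list did not pass (camera adjusted p = 0.314). Further called genes were Fam101b (2.74, SE 0.37), Klf13 (2.33, SE 0.66, adjusted p = 0.0267) and Emb (2.01, SE 0.57, adjusted p = 0.0267).

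Luminal mammary genes were lower in TEneg, with 2 of 5 tested members past the threshold and 3 adjusted over the list alone (camera adjusted p = 0.0121, and adjusted p = 0.342 with an estimated correlation). Wfdc18 fell by 1.13 on the log2 scale (SE 0.26, adjusted p = 0.0044), from 136 ± 55.3 to 57.03 ± 23.4 per 10000, and the milk casein gene Csn3 fell by 0.81 (SE 0.23, adjusted p = 0.0267, 3 of 4 libraries), from 136 ± 33.7 to 72.6 ± 23.9 per 10000. Lcn2 (−0.50) and Trf (−0.35) did not pass. The luminal list took 4.76 ± 0.711% of TEpos and 2.70 ± 0.922% of TEneg transcripts. Of 5 epithelial genes tested, 0 passed and 2 passed adjusted over the list alone (camera adjusted p = 0.0182, and adjusted p = 0.342 with an estimated correlation). Epcam had a log2 fold change of −0.76 (SE 0.27, adjusted p = 0.0947), the keratin gene Krt18 of −0.78 (adjusted p = 0.102) and Krt8 of −0.60 (adjusted p = 0.215). Without the large TEneg cell of library 2, Epcam passed at −1.04 (adjusted p = 0.0029, with a range over all alternatives of 0.0022 to 0.601). Without library 3 the epithelial (camera adjusted p = 0.2096) and luminal (0.0529) calls were lost, as they were with at least 1500 transcripts per cell (0.126 and 0.0742) and without TEneg cells above every TEpos cell in basal genes (0.0557 and 0.0622) or in endothelial, basal or immune genes (0.0987 and 0.165). Without those above in endothelial genes the epithelial call alone was lost (0.0505).

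Of 17 immediate early and stress genes, 3 fell and 5 fell adjusted over the list alone (camera adjusted p = 0.000777, adjusted p = 0.342 with an estimated correlation, and 0.398 without cells with 2 or more leukocyte transcripts). The last setting left 4 of 18 TEpos cells in library 1 and 258 genes tested, so the lost call cannot be credited to leukocyte transcripts alone. Fos fell by 1.01 (SE 0.26, adjusted p = 0.0119) and Zfp36, which promotes decay of AU-rich transcripts, by 1.198 (SE 0.30, adjusted p = 0.0106), while Jun, at −0.95, did not pass (adjusted p = 0.0596). Phlda1 fell by 0.89 (SE 0.20) and Clic6 by 1.31 (SE 0.34, adjusted p = 0.0119). Among 73 cytosolic ribosomal protein genes only Rpl39 was called (−0.61, adjusted p = 0.0364), with 0 adjusted over the list alone. The list lay lower (camera adjusted p = 2.46e-05, and adjusted p = 0.342 with an estimated correlation), with a median log2 fold change of −0.19. Leukocyte (0 of 8), monocyte and macrophage (0 of 7, and 1 higher adjusted over the list alone), neutrophil (0 of 7), proliferation (0 of 4) and oxidative phosphorylation genes (0 of 12) did not pass, with camera adjusted p of 0.711, 0.0651, 0.526, 0.711 and 0.49975. For proliferation the test pointed up and the median was −0.10. Lyz2 was 2.17 higher in TEneg (adjusted p = 0.0761). By the fry test of limma only the mesenchymal list passed (adjusted p = 0.0039), and the epithelial, luminal and immediate early lists (0.169 each) and the ribosomal list (0.111) did not.

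The count of 31 moved with several choices. It was 20 without the library block, 19 without library 1 and 55 without the large TEneg cell, and Csn3, Emb, Klf13, Fos, Zfp36, Clic6, Wfdc18, Phlda1, Pmepa1, Bgn, Vim and Rpl39 lost their calls in at least 1 alternative. Acta2, itself a member of the basal list, stood at 1.11 (adjusted p = 0.346) once TEneg cells above every TEpos cell in that list were left out.

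The second comparison set Ecad-negative cells sorted from blood against Ecad-negative tumour cells. The leukocyte, monocyte and macrophage, and neutrophil lists were higher in BEneg and the luminal and epithelial lists were lower, while Sparc, Acta2 and Col4a1 fell, Vim rose (a call lost with means of cells) and the mesenchymal list was not called. The calcium-binding protein genes S100a8 and S100a9, abundant in neutrophils, reached 322 ± 126.4 and 350 ± 123.03 transcripts per 10000 in BEneg against 9.43 ± 3.34 and 13.3 ± 10.1 in TEneg (n = 4 libraries), log2 fold changes of 5.46 (SE 0.34) and 5.28 (SE 0.40, edgeR adjusted p = 2.34e-11). Lysozyme transcripts rose by 5.94 for Lyz2 (SE 0.32, 72.1 ± 23.98 against 1.94 ± 1.75 per 10000) and 5.54 for Lyz1. Retnlg, a resistin-like gene of neutrophils, rose by 6.51 (SE 0.28, adjusted p = 1.48e-16). Of 490 genes 201 were called by edgeR, 117 higher and 84 lower in BEneg.

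All 8 tested leukocyte genes rose in BEneg, also adjusted over the list alone, among them Rac2 (6.13), Srgn (4.58) and Cd52 (4.37) (camera adjusted p = 1.05e-05, and adjusted p = 0.0837 with an estimated correlation). Of 13 leukocyte-list genes measured, these 8 passed the filter on low counts. The leukocyte gene Ptprc was too low to test in any population. It had 0, 0, 0 and 1 transcripts in BEneg libraries 1 to 4, and 0 in TEpos, TEneg and BEpos. All 7 monocyte and macrophage genes rose, over all genes and adjusted over the list alone, with the immune receptor adaptors Tyrobp at 5.16 and Fcer1g at 4.94 (camera adjusted p = 7.56e-06, and adjusted p = 0.161 with an estimated correlation). Ly6c2, a monocyte surface antigen, had 88 transcripts in BEneg and 2 in TEneg, a ratio of 110 (95% interval 29.6 to 923). The chemokine receptor gene Ccr2 had 59 and 0, at least 49.2-fold higher, and Pygl 40 and 0, at least 33.3-fold higher. Of 7 neutrophil genes 6 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 7.45e-05, and adjusted p = 0.0837 with an estimated correlation). The cytokine gene Il1b rose by 6.43, Mmp9 had 89 transcripts against 2 (ratio 111, 29.9 to 933), and the member that fell was Ltf (−1.76, SE 0.53, adjusted p = 0.0078, 3 of 4 libraries), which mammary epithelium also makes. Alox5ap, needed for leukotriene synthesis, rose by 6.27, and Slfn4 had 51 transcripts against 1 (ratio 128, 21.9 to 5135).

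Each of the 60 BEneg cells held S100a9 transcripts and at least 4 transcripts of the leukocyte list, and 58 of them lay above every TEpos cell in the leukocyte share. Leukocyte genes took 1.26 ± 0.265% of BEneg and 0.0793 ± 0.0278% of TEneg transcripts, monocyte and macrophage genes 3.14 ± 0.750% against 0.134 ± 0.0878%, and neutrophil genes 8.17 ± 2.84% against 0.369 ± 0.0690%, each higher in 4 of 4 libraries. S100a9 was also found in 84.7 ± 14.8% of TEneg and 87.1 ± 6.0% of TEpos cells, and after thinning to 500 transcripts in 47.4 ± 33.4%, 47.5 ± 10.8% and, for BEneg, 88.3 ± 5.25%. Tyrobp was found in 95.3 ± 3.29% of BEneg, 26.5 ± 6.45% of TEneg and 29.6 ± 17.7% of TEpos cells.

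**Figure D1:**
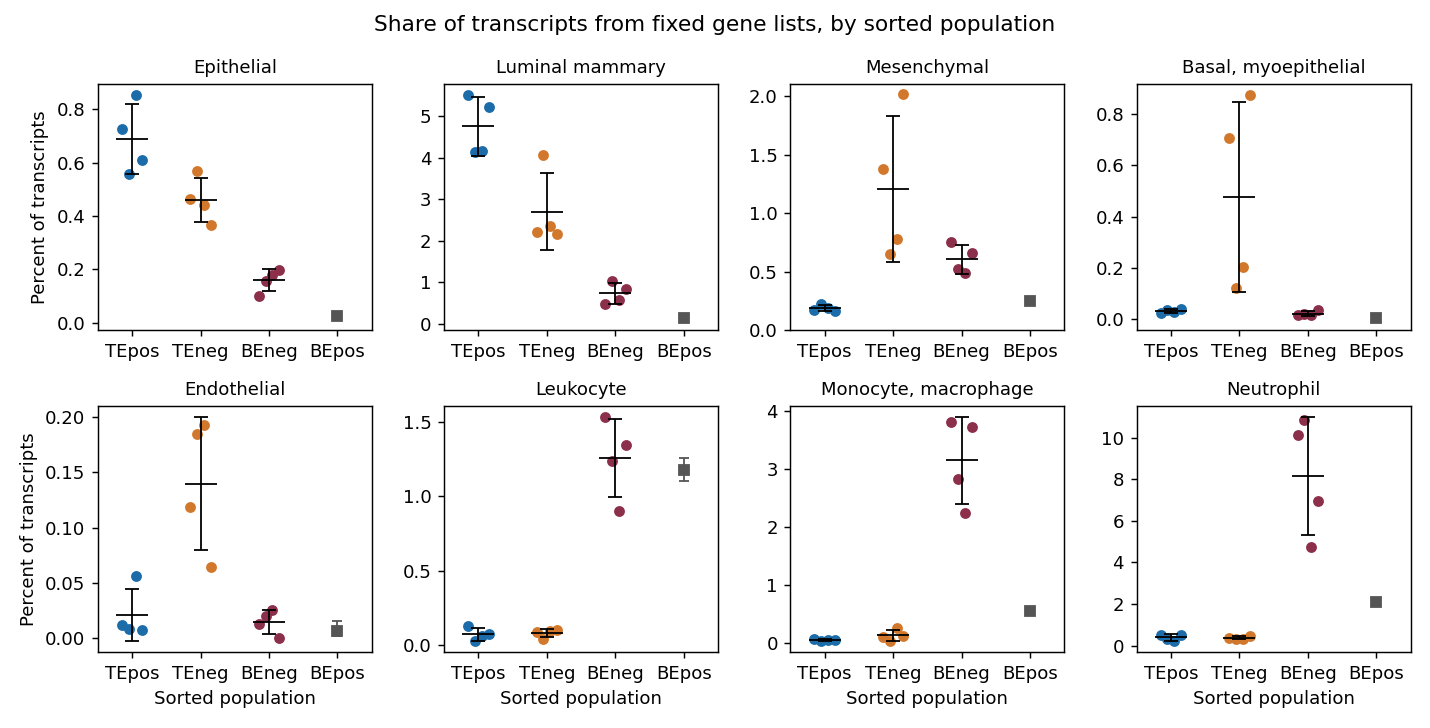
Share of transcripts (%) from 8 gene lists in Ecad-positive (TEpos) and Ecad-negative (TEneg) tumour cells and Ecad-negative (BEneg) and Ecad-positive (BEpos) cells sorted from blood, with dots for libraries, bars for the mean ± SD of 4 libraries, and a square with its 95% Poisson interval for BEpos, which was in 1 library. Neutrophil genes averaged 8.17% in BEneg against 0.386% in TEpos, and luminal genes 0.726% against 4.76%.

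All 5 luminal mammary genes fell from TEneg to BEneg, also adjusted over the list alone (camera adjusted p = 0.0037, and adjusted p = 0.323 with an estimated correlation). Csn3 fell by 2.24, to 13.7 ± 8.74 per 10000, Wfdc18 by 2.34, to 10.4 ± 3.89, Trf by 1.79 and Lcn2 by 1.19. Of 5 epithelial genes 4 fell, over all genes and adjusted over the list alone, with Krt18 at −2.21 (SE 0.48), Krt8 at −1.95 and Epcam at −1.83 (SE 0.41) (camera adjusted p = 0.0270, and adjusted p = 0.361 with an estimated correlation). The epithelial call was also lost with scaling by total transcripts alone (0.0615), with means of cells (0.173) and without library 1 (0.0621). Cdh1 did not pass (−0.25, SE 0.45, adjusted p = 0.706, lower in 2 of 4 libraries), at 3.87 ± 1.59 per 10000 in BEneg.

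Of 7 mesenchymal genes 3 rose and 4 fell in BEneg, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.577). The 3 that rose were S100a4 (4.41, SE 0.48), Vim (1.37, SE 0.26, 24.6 ± 2.65 per 10000 in BEneg) and Tgfbi, all 3 of which leukocytes also express. With means of cells in limma Vim was at 0.66 and lost its call (adjusted p = 0.0814, with a range over all alternatives of 5.57e-06 to 0.0814). Those that fell were Acta2 (−4.33, SE 0.57), Sparc (−3.21, SE 0.31, to 3.67 ± 1.64 per 10000), Cald1 (−3.00, SE 0.64) and Bgn (−1.96, SE 0.65). Col4a1 fell by 4.41 (SE 0.49), Sparcl1 by 3.87, Igfbp3 by 3.49 and Nedd4 by 3.45. Col4a2 had 3 transcripts in BEneg and 147 in TEneg, a ratio of 19.6 in favour of TEneg (6.57 to 96.1). The same ratio was 22.2 for Srebf1 (2 and 111 transcripts, 6.001 to 186) and 8.93 for Hspa1b (3 and 67, 2.93 to 44.4).

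Of 4 proliferation genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.903). The chromatin protein gene Hmgb2 rose by 2.53, and Stmn1 had 2 transcripts in BEneg against 41 in TEneg, a ratio of 8.20 in favour of TEneg (2.13 to 69.96). The interferon-induced gene Ifitm3 rose by 1.22. Immediate early genes (2 higher and 4 lower of 17, the same adjusted over the list alone, camera adjusted p = 0.230), oxidative phosphorylation (0 and 2 of 12, 1 lower adjusted over the list alone, adjusted p = 0.198), TGF-beta response (1 and 1 of 3, the same adjusted over the list alone, adjusted p = 0.771) and ribosomal protein genes (3 and 6 of 73, 2 and 2 adjusted over the list alone, adjusted p = 0.226) were not called as lists. The median and the camera direction differed in sign for proliferation, and the median (−0.46) and mean (0.26) for TGF-beta response. By the fry test of limma the leukocyte, monocyte and macrophage, neutrophil, luminal and epithelial lists passed (adjusted p = 3.35e-05, 3.83e-05, 4.04e-06, 0.0017 and 0.0054), as did oxidative phosphorylation, lower in BEneg (0.0236). With scaling by total transcripts alone the median of all genes moved to −0.49 and 286 genes were called, 99 higher and 187 lower. With means of cells in limma 103 were called higher and 153 lower.

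The third comparison set Ecad-negative cells sorted from blood against Ecad-positive tumour cells. The same groups of immune genes were higher in BEneg and luminal and epithelial genes were lower. Csn3 went from 136 ± 33.7 per 10000 in TEpos to 13.7 ± 8.74 in BEneg (log2 fold change −3.05, SE 0.29), Wfdc18 fell by 3.47 (SE 0.33) and Epcam by 2.59 (SE 0.38, edgeR adjusted p = 2.46e-06), from 15.1 ± 3.83 to 2.12 ± 1.03. Lyz2 rose by 8.11 (SE 0.38, edgeR adjusted p = 6.43e-16), from 0.350 to 72.1 ± 23.98 per 10000, S100a9 by 5.28 (SE 0.38) and Vim by 3.85 (SE 0.31, 24.6 ± 2.65 against 2.15 ± 0.587). Cdh1 did not pass (−0.24, SE 0.44, adjusted p = 0.702, lower in 3 of 4 libraries). Of 490 genes 236 were called by edgeR, 133 higher and 103 lower.

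All 5 luminal genes fell, also adjusted over the list alone, Trf by 2.14 and Lcn2 by 1.69 among them (camera adjusted p = 0.0010, and adjusted p = 0.241 with an estimated correlation). Of 5 epithelial genes 4 fell, also adjusted over the list alone, with Krt18 at −2.99, the tight junction gene Cldn3 at −2.97 and Krt8 at −2.55 (camera adjusted p = 0.0056, and adjusted p = 0.241 with an estimated correlation). All 8 leukocyte and all 7 monocyte and macrophage genes rose, as did 6 of 7 neutrophil genes, with Ltf lower (−2.03), and each of these counts was unchanged adjusted over the list alone (camera adjusted p = 2.33e-05, 1.04e-05 and 0.000290, and adjusted p = 0.0969, 0.168 and 0.0969 with an estimated correlation). Lyz1 rose by 6.69, Retnlg by 5.997, S100a8 by 5.52 and Tyrobp by 5.31. Ccr2 (59 transcripts and 0) was at least 50.97-fold higher in BEneg, Tgfbi (60 and 0) at least 51.8-fold and Bin2 (43 and 0) at least 37.1-fold. The ratio was 119 for Alox5ap (138 and 3 transcripts, 39.95 to 585), 135 for Sfpi1, a myeloid transcription factor gene (52 and 1, 23.1 to 5424), 114 for Ly6c2 (88 and 2, 30.6 to 956) and 76.9 for Mmp9 (89 and 3, 25.5 to 380).

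Of 17 immediate early and stress genes 9 fell and 1 rose, also adjusted over the list alone, with Cyr61 at −3.18, Fosb at −2.99, Jun at −1.87 and Fos at −0.87 (camera adjusted p = 0.0056, and adjusted p = 0.319 with an estimated correlation). Of 73 ribosomal protein genes 22 fell and 3 rose, and 19 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0017, and adjusted p = 0.290 with an estimated correlation, 0.136 with the stricter filter and 0.302 with at least 1500 transcripts per cell, where BEneg had sums in libraries 1 and 2 only). Mesenchymal genes were not called as a list (3 rose and 1 fell of 7, the same adjusted over the list alone, median 0.39, camera adjusted p = 0.189). S100a4 rose by 5.73, while Sparc (0.24) and Acta2 (−0.54) did not pass. Also not called were proliferation (1 higher and 1 lower of 4, the same adjusted over the list alone, adjusted p = 0.821), oxidative phosphorylation (0 and 4 of 12, the same adjusted over the list alone, adjusted p = 0.0817) and TGF-beta response (1 and 1 of 3, 1 and 2 adjusted over the list alone, adjusted p = 0.821), the last with a negative median and a positive mean. For proliferation the median was 0.39 and the mean −0.09. Hmgb2 rose by 2.17 and Ifitm3 by 1.96, while Wbp5 fell by 2.73. In favour of TEpos, the ratio was 17.6 for Srebf1 (91 transcripts against 2, 4.72 to 147), 13.7 for Stmn1 (71 against 2, 3.65 to 115) and 9.003 for Hspa1b (70 against 3, 2.96 to 44.7). By the fry test of limma each list called by camera passed, with the immediate early list at the highest adjusted p (0.011), as did mesenchymal genes, higher in BEneg (0.0050), and oxidative phosphorylation, lower (0.0058). With scaling by total transcripts alone the median of all genes moved to −0.48 and 298 genes were called, 110 higher and 188 lower. With means of cells in limma 296 were called, 106 higher and 190 lower.

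Lists with fewer than 3 tested genes have shares of transcripts alone (mean of 4 libraries in TEpos, TEneg and BEneg). Stem cell associated genes took 0.271%, 0.246% and 0.156%, interferon response genes 0.201%, 0.232% and 0.440%, and glycolysis and hypoxia genes 0.372%, 0.342% and 0.320%. Platelet genes took 0.00077%, 0.0025% and 0.0090%, erythroid genes 0.0109%, 0.0125% and 0.0137%, T and NK cell genes 0.0130%, 0.0313% and 0.0424%, B cell genes 0.0084%, 0.0173% and 0.0061%, and MHC class II genes 0.0274%, 0.0315% and 0.0750%. Interferon response genes were higher in BEneg than in TEneg in 4 of 4 libraries.

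Per cell, Cdh1 and Vim were compared as shares of cells with at least 1 transcript, without a test between cells. Cdh1 was found in 60.7 ± 9.41% of TEpos, 41.9 ± 20.1% of TEneg and 34.7 ± 13.9% of BEneg cells (SD, n = 4 libraries), and in 1 of 20 BEpos cells. With every cell thinned to 500 transcripts the values were 27.3 ± 14.2%, 16 ± 9.35% and 19 ± 5.55%, and 0 of 20 BEpos cells, which allows a share of up to 16.8% of cells with a transcript. Vim was found in 32.1 ± 7.54% of TEpos, 63.95 ± 14.3% of TEneg, 73.7 ± 15.4% of BEneg and 17 of 20 BEpos cells, and after thinning in 5.48 ± 4.54%, 39.4 ± 14.97%, 59.2 ± 17.9% and 30%. Both genes were found in 20 of 71 TEpos cells, 23 of 69 TEneg cells, 13 of 60 BEneg cells and 1 of 20 BEpos cells. Independent detection in the pooled cells would give 19.6%, 28.6%, 24.4% and 4.2%, against 28.2%, 33.3%, 21.7% and 5.0% observed.

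**Figure D2:**
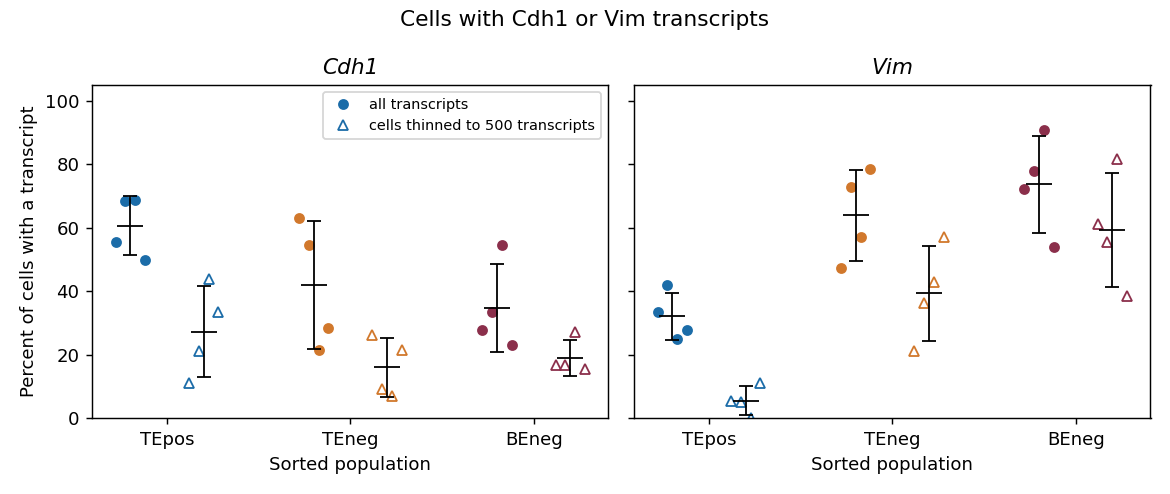
Percent of cells with at least 1 Cdh1 or Vim transcript in TEpos, TEneg and BEneg, from all transcripts and with each cell thinned to 500 transcripts, with dots for libraries and bars for the mean ± SD of 4 libraries. Vim was found in 32.1% of TEpos and 73.7% of BEneg cells before thinning and in 5.48% and 59.2% after.

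Ecad-positive cells sorted from blood were present in library 1 only, so no test was made and values carry counting intervals. BEpos held transcripts of T, NK and B cells and of MHC class II genes at higher shares than the other populations. The T and NK cell list took 0.571% of BEpos transcripts (0.518 to 0.627), the B cell list 0.315% (0.276 to 0.357) and MHC class II genes 0.497% (0.448 to 0.550), against 0.0571%, 0.0245% and 0.106% in BEneg of the same library. Cd3d, a T cell receptor subunit gene, had 47 transcripts in BEpos and 1 in BEneg, Ccl5 93 and 4, and the B cell receptor gene Cd79a 56 and 1. Of 20 BEpos cells, 17 lay above every TEpos cell in the T and NK share, 10 in the B cell share and 20 in the leukocyte share. Neutrophil genes took 2.11% of BEpos and 10.1% of BEneg transcripts, with S100a9 at 100.3 per 10000 (93.2 to 107.7) against 425 (400 to 452), and ribosomal protein genes took 35.5% (35.1 to 35.96) against 16.2%. Epithelial genes took 0.0240% (0.0142 to 0.0379) and luminal genes 0.135% (0.110 to 0.164), against 0.102% and 0.478% in BEneg and 0.728% and 5.52% in TEpos of that library. Much of the luminal share in blood cells came from 1 gene, Lcn2. It gave 48 of the 101 luminal transcripts in BEpos, and 62 transcripts (25.3 per 10000) in BEneg. Cdh1 had 1 transcript in 75125 in BEpos, Epcam 3, Krt8 1 and Krt18 1. Other shares in BEpos were 0.249% for mesenchymal, 0.557% for monocyte and macrophage and 1.18% for leukocyte genes.

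In experiment (i), where all cells had been sorted as Ecad-positive, Cdh1, Epcam, Krt8 and Krt18 transcripts were found in fewer cells of library 2 than of library 1, with no test made between 2 single libraries. Cdh1 was found in 85.3% of the 95 cells of library 1 (76.5 to 91.7) and 30.8% of the 65 cells of library 2 (19.9 to 43.4), a mean of 58.02%, and Vim in 8.42% (3.71 to 15.9) and 38.5% (26.7 to 51.4), a mean of 23.4%. After thinning to 500 transcripts Cdh1 was found in 43.2% (33.03 to 53.7) and 20% (11.1 to 31.8). Epcam was found in 88.4% and 21.5%, Krt8 in 91.6% and 23.1%, and Krt18 in 97.9% and 38.5%, and after thinning these 3 were found in 41.1% and 10.8%, 50.5% and 18.5%, and 60% and 23.1%. The epithelial list took 1.18% and 0.477% of transcripts, the luminal list 3.10% and 1.47%, the mesenchymal list 0.0788% and 1.64%, the monocyte and macrophage list 0.0364% and 0.791%, and the MHC class II list 0.0207% and 0.426%. Sparc was found in 21.1% and 64.6% of cells and Apoe in 25.3% and 76.9%. Median transcripts per well were 3044 and 735. Cdh1 and Vim were found together in 7 of 95 and 8 of 65 cells. Experiments (i) and (ii) were not compared, since experiment and sorted group cannot be separated.

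Loci on GRCm38 were as follows. Cdh1 (ENSMUSG00000000303) lies on chromosome 8 from 106603351 to 106670246, Vim (ENSMUSG00000026728) on chromosome 2 from 13573927 to 13582826, and Epcam (ENSMUSG00000045394) on chromosome 17 from 87635979 to 87651129. Sparc (ENSMUSG00000018593) lies on chromosome 11 from 55394500 to 55423183, Col4a1 (ENSMUSG00000031502) on chromosome 8 from 11198423 to 11312826, and Acta2 (ENSMUSG00000035783) on chromosome 19 from 34241090 to 34255590. Csn3 (ENSMUSG00000001622) lies on chromosome 5 from 87925579 to 87932665, S100a9 (ENSMUSG00000056071) on chromosome 3 from 90692632 to 90695721, and Lyz2 (ENSMUSG00000069516) on chromosome 10 from 117277331 to 117282321. All are protein-coding, and the counts cover whole genes, mostly through their 3' ends.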

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

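Of the tests below, that of cells without luminal content in the Ecad-negative tumour gate was set before its result was seen, and those of endothelial, basal and immune cells and of other splits of the sums were chosen after. For cells without luminal content, the requirement that the bound be passed by more than the spread was added after results had been seen.

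Mesenchymal genes were higher in TEneg than in TEpos, and the labels name Ecad sorting alone, so endothelial, basal and immune cells may have entered the Ecad-negative gate. With the 16 TEneg cells above every TEpos cell in endothelial genes left out, the median log2 fold of 6 mesenchymal genes was 1.66 against 2.07 in all cells (Acta2 left out, Tgfbi at its lower bound). With the 15 cells above in basal genes left out the median was 1.99. These values argue against the cells left out, in either case, as the whole cause. They cannot exclude either type, since cells of that type below the highest TEpos cell would have stayed in. In library 4, 0 TEneg cells lay above in endothelial genes, yet these genes took 0.0642% of TEneg against 0.0073% of TEpos transcripts. Acta2, a member of the basal list, went from 3.78 (SE 0.43) to 1.11 (SE 0.55) without the 15 cells and lost its call. Leaving out cells above in endothelial, basal or immune genes together took away 36 of the 69 TEneg cells. It left 7, 11, 7 and 8 in libraries 1 to 4. The median was then 1.48 (median SE 0.54) and only Sparc stayed called. Vim went from 2.48 (SE 0.32) to 1.42 (SE 0.54) and lost its call through a smaller fold and a wider spread. A mixture of these types therefore cannot be told apart from a change in tumour cells. In the 17 TEneg cells whose luminal share reached the lower quartile of TEpos cells, mesenchymal genes of no basal list took 0.461 ± 0.179% against 0.174 ± 0.0266% in TEpos and 0.170 ± 0.0525% in the TEpos cells chosen in the same way, higher in 4 of 4 libraries but above 2 times the TEpos mean by less than the spread, whereas the mean over these cells, each weighted alike, was 0.586 ± 0.143% against 0.173 ± 0.0760% and lay above that bound by more than its spread. The 2 weightings part mainly in library 2 (0.270% against 0.681%). In the 17 TEneg cells Sparc was higher than in TEpos cells chosen in the same way in 4 of 4 libraries (8.45 to 23.3 per 10000 against 1.59 to 6.73). Vim was higher in 2 of 4 (1.74, 1.21, 0 and 13.94 against 0.906, 2.28, 2.76 and 1.70). The share of 0.461% met the bound as first set, but not the later requirement of passing it by more than the spread. With Vim divided as well, cells without luminal content stay open as a cause. Fibroblasts stay open too, since 9 of 69 TEneg cells lay above every TEpos cell in fibroblast genes and no test left cells out by that list. So do doublets (not tested) and a partial transition of tumour cells towards a mesenchymal state. The transition is a hypothesis that imaging or lineage tracing of Sparc-positive and Epcam-positive cells in the gate would test.

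The populations share libraries, so the real split of the 8 sums of each comparison was set against the splits that part the sums of every library, which number 8 and are too few for a share under 0.05. The real split was the only 1 of these to call as many genes in fits of 2 populations, with 30 genes for TEneg versus TEpos, 168 for BEneg versus TEneg and 242 for BEneg versus TEpos, and the highest other was 0 in each. The other fitted splits, which put both sums of some libraries in the same group, called at most 8, 0 and 0.

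A single library stood apart from the other 3 by its gap relative to the range in 10 of 114 groups of 4 values, where about 5.7 would arise by chance. Luminal genes took 4.08% of TEneg library 2, which holds the largest cell, against 2.22%, 2.35% and 2.15%. Proliferation genes took 0.220% of TEpos library 1, against 0.395%, 0.389% and 0.366%. B cell genes took 0.0245% of BEneg library 1, against 0 in the others. Library 1, the only one with BEpos wells, also had the highest B cell share in TEpos (0.0219%) and TEneg (0.0404%). Erythroid genes took 0.0507% of BEneg library 3, against at most 0.0041%. Endothelial genes took 0.0565% of TEpos library 3, against at most 0.0118%. Immediate early genes took 2.17% of TEpos library 1, against 1.55%, 1.56% and 1.58%. Lyz2 had 107.8 transcripts per 10000 in BEneg library 4, against 64.1, 57.3 and 59.1. Retnlg had 2.56 per 10000 in TEpos library 4, against 1.35, 1.255 and 1.33. In BEneg library 1, Sparc had 1.22 per 10000 against 4.74, 4.22 and 4.49, and Vim 28.6 against 22.9, 23.7 and 23.4. In library 3 of experiment (i), which no comparison used, Rhox8 took 40.04% of the transcripts of the only cell of at least 500 transcripts.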

How the results depend on the processing

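Leaving out the largest TEneg cell and leaving out TEneg cells above every TEpos cell in endothelial, basal or immune genes were chosen after the data were examined, and the other alternatives before.

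For TEneg versus TEpos, the 31 genes called became 20 without the library block, 99 without a filter on low counts, 15 with cells thinned to 500 transcripts, 55 without the largest TEneg cell, and 20, 17 and 10 without TEneg cells above TEpos in endothelial, basal, or endothelial, basal or immune genes. Leaving out 1 library gave 19 (without library 1) to 42 (without library 2). Of the 20 genes called without the block, 20 were among the 31, as were 11 of 15 with thinned cells and 30 of 55 without the largest cell. For BEneg versus TEneg, the 201 became 461 without the filter, 123 with at least 1500 transcripts per cell and 61 with thinned cells. For BEneg versus TEpos, the 236 became 581, 133 and 69. The number of genes tested moved too, in each comparison. It went from 490 to 11431 without the filter, 449 with at least 1500 transcripts per cell and 156 with thinned cells. Counts under these settings are therefore not on one scale, and a smaller count need not mean a smaller share of the genes tested. The minimum of 1500 also left BEneg sums in 2 of 4 libraries (fewer than 3 cells in libraries 3 and 4), so the falls to 123 and 133 cannot be credited to the minimum per cell alone.

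The sign of the Cdh1 log2 fold change, which passed in neither direction, turned for TEneg versus TEpos (0.01) to −0.11 without the block, −0.12 with DESeq2, −0.36 without the filter, −0.00641 with the stricter filter, −0.73 with means of cells and −0.28 without the largest cell, and ran from −0.51 (without library 2) to 0.51 (without library 3). For BEneg versus TEneg (−0.25) it turned to 0.40 with means of cells and 0.15 without the largest cell, and ran from −0.52 (without library 3) to 0.0793 (without library 2).

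With an estimated correlation, 0 gene lists were called in each comparison, against 5, 5 and 7 with the preset one. Calls lost under other alternatives were the epithelial and luminal lists for TEneg versus TEpos with at least 1500 transcripts per cell, without library 3, and without TEneg cells above TEpos in basal, or endothelial, basal or immune genes, the epithelial list alone without those above in endothelial genes, and the immediate early list without cells with 2 or more leukocyte transcripts. The epithelial list for BEneg versus TEneg was lost with total transcripts only, means of cells and without library 1, and the ribosomal list for BEneg versus TEpos with the stricter filter and with at least 1500 transcripts per cell.

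Cells with Cdh1 fell with thinning to 27.3% of TEpos, 16% of TEneg, 19% of BEneg and 0 of BEpos, and to 50% of TEpos with no minimum per cell. Cells with Vim went with thinning to 5.48% of TEpos, 39.4% of TEneg and 30% of BEpos. With at least 1500 transcripts they went to 44.3% of TEpos and 92.9% of BEneg, the latter from 2 libraries (11 of 12 cells).

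Of the other values of named genes, the call or its absence held in 401 and changed in 33 (gained) and 75 (lost) for TEneg versus TEpos, in 594 with 12 lost for BEneg versus TEneg, and in 513 with 8 lost for BEneg versus TEpos. Named genes that failed the filter in an alternative had no value there and are not counted. With thinned cells, for example, 13 of 35 were left for BEneg versus TEpos. These counts thus describe only genes that stayed tested. Leaving out cells with 2 or more leukocyte transcripts left 0 BEneg cells, so neither blood comparison was run there.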

Other observations

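Of the tests in this part, those of low-yield blood wells, of fewer transcripts per cell in library 2 of experiment (i) and of immune cells for its Epcam, Krt8 and Krt18 were set before their results were seen, and the others after. The test of low-yield blood wells was corrected to include BEpos wells after results had been seen.

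Library 2 of experiment (i) held basal genes at 0.431% and fibroblast genes at 0.270% of transcripts, against 0.0138% and 0.0943% in library 1. EMT transcription factors took 0.1501% against 0.0556%, and endothelial genes 0.0660% against 0.0018%. Acta2 was found in 35.4% of its cells against 3.16%, and Cd74 in 20% against 3.16%.

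Luminal and epithelial transcripts were present at a low level in cells sorted from blood, each of which also held at least 4 leukocyte-list transcripts, so background RNA from tumour cells may have reached leukocytes or their wells. In library 1 the ratio of Csn3, Wfdc18, Trf, Epcam, Krt8 and Krt18 transcripts per cell, BEpos over BEneg, was 0.789 (0.429 to 1.5 from resampling cells), while the ratio of total transcripts was 2.75. In wells sorted from blood with under 500 transcripts, these genes stood at 0.426 (0.300 to 0.667 from resampling wells) of their level in wells above, with a ratio of totals of 0.302. By library they stood at 0.221, 0.410, 0.542 and 0.530, with ratios of totals of 0.227, 0.296, 0.289 and 0.394. A background equal in every well, as the only source, would give 1. The interval of 0.300 to 0.667 does not hold 1, although that of BEpos over BEneg does. The level set for such a background was lower, at least 0.5, with libraries 1 and 2 below it and libraries 3 and 4 above. That interval holds both 0.5 and the ratio of totals, the libraries differ, and these tests part. A contribution of such a background therefore cannot be told apart from transcripts of the cells themselves. With the 4 libraries pooled, the ratio of Cdh1 to Epcam, Krt8 and Krt18 in BEneg was 5.73 times that of TEpos (3.27 to 10.04) and 3.26 times that of TEneg (1.86 to 5.72), with intervals from counting error alone and 26 Cdh1 transcripts, and it was above 1 in each library (3.14 to 8.64 and 1.94 to 9.5), although the interval held 1 in library 4 against TEpos and in libraries 1 and 4 against TEneg, which argues, by the pooled counts, against the same background as their only source. Whether the sorted cells were tumour cells could be tested by reading the PyMT transgene, which was not analysed here.

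In experiment (i), library 2 held Cdh1 in fewer cells than library 1, although both were sorted as Ecad-positive. Fewer transcripts per cell are not the whole cause, since after thinning Cdh1 was found in 20% (11.1 to 31.8) against 43.2% (33.03 to 53.7) of cells. Cells of another type may be present, since leukocyte, monocyte and macrophage, and MHC class II genes took 7.87, 21.7 and 20.6 times the share in library 1. With the 35 of 65 cells that held 2 or more immune transcripts left out, Cdh1 was found after thinning in 16.7% (5.64 to 34.7), no nearer to library 1 than before but with an interval that still overlapped that of library 1, so immune cells stay open for Cdh1, whereas Epcam, Krt8 and Krt18 were found in at most 20% (Krt18, 7.71 to 38.6, against 60% in library 1, 49.4 to 69.9), which argues against immune cells as the whole cause for these 3 genes. After thinning Sparc was found in 22 of the 30 cells left and in 2 of 95 in library 1, so non-immune stromal or mesenchymal cells are a candidate cause that was not tested, no biological difference between the libraries is given in the labels, and re-sorting with a second epithelial marker would test it.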
